A study of Zea mays with 4 samples.

How the data were processed

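Gene expression was measured by RNA sequencing of stem tissue from 2 maize lines, with 2 libraries for the high line and 2 for the low line. Per the labels' protocols, poly-A RNA was enriched from total RNA and made into indexed TruSeq libraries, which were sequenced from both ends. The kit as labelled does not mark strand, so reads of overlapping or antisense genes cannot be told apart. Per the submitters' processing notes, the tools were TopHat2, Cufflinks 2.2.1, Cuffdiff and DESeq 1.28.0 and the genome build was B73 RefGen_v4. Which of these aligned reads or counted them, and how reads with several best matches were treated, is not given in the sources used here. The deposited comparison has DESeq2 in its name. Reads of near-identical copies could therefore be split, dropped or assigned at random.

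The deposited table gave, per the file headers, a count per gene and library, and these counts were whole numbers with totals that differed between libraries, so they were used as raw counts. The authors deposited FPKM values beside them, per the file headers, whose exact scaling is not given in the sources used here. The authors' deposited comparison of the high with the low line held a log2 fold change, a p-value and a false discovery rate per gene, per the file headers. The table listed 25633 genes, 25582 with Zm00001d and 51 with GRMZM identifiers, each with at least 20 reads over the 4 libraries, so genes below that were not analysed here. It contained 1 further entry without a gene name and without counts, which was left out. A total of 5379 count cells were blank. They were read as 0, because FPKM there was at most 0.11 and was 0 in 99.78% of them. Descriptions came from the deposited table for 23772 genes. Of 24289 genes with 1 Entrez identifier, 22955 matched a gene table of the assembly Zm-B73-REFERENCE-NAM-5.0, which was used only for symbols and for which genes are neighbours. Because the builds differ, coordinates are not reported here.

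Group membership was taken from the line label of each sample. Library totals ranged from 20535283 to 64932808 reads. Scaling factors from the trimmed mean of M-values (TMM) were 0.987 and 0.906 for high replicates 1 and 2 and 1.082 and 1.033 for low replicates 1 and 2. CPM values are counts divided by the TMM-scaled library size and multiplied by 1e6, and log2 CPM used a pseudocount of 2. A count of 0 was given an upper limit of 3 reads over the line, and a fold against it uses the smaller of the other line's mean and pooled CPM. The 95% intervals of ratios with 1 to 3 reads in one line come from the exact binomial split of the reads and cover counting error only.

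The main test was edgeR 4.0.16 in R 4.3.3: filterByExpr with its minimum count of 10, TMM factors, a quasi-likelihood fit with the line as the only term, and Benjamini-Hochberg adjustment at 0.05. It tested 23360 genes, and 2273 were removed by the filter. The 19 gene lists were defined by patterns on descriptions and symbols. A list with at least 5 tested members, which held for 18 lists, was tested with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 18. For each list the genes passing were counted over all genes and adjusted over the list alone. Members of a list were counted as tested only after the low-count filter.

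Named genes followed a rule. Its first part took the 8 largest rises and the 8 largest falls among called genes with a mean of at least 10 CPM, no overlap between lines and an informative description. Its second part took the called member of each list with the smallest adjusted p in each direction, at a mean of at least 1 CPM. Its last part took a fixed set of stature and stem symbols, of which 19 were used here and 10 matched; 1 further gene of the set is not reported here. The test, its threshold, the lists, the naming rule and most alternatives were chosen before the data were examined. Other genes named in the text were chosen after their values were seen.

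The alternatives were DESeq2 size factors or upper-quartile factors in place of TMM, no filter or a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom, glmTreat against a 1.5-fold change, a minimum of 2-fold, the replicate number as a block, and leaving out each library in turn. For lists, camera with an estimated correlation and fry were added. Alternatives chosen after seeing the data were thinning high replicate 1 to the mean total of the other libraries (21955160 reads), limma on log2(FPKM + 1), lists that also matched protein domain names, and other thresholds for genes read in a single line. A planned change of pseudocount applied only to a table without counts and was not run.

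The procedure was tested on simulated counts with the fitted spread, 2 libraries against 2 and 22761 genes, for the comparison of the high with the low line. With 50 genes changed at each size, edgeR recovered 6% of 4-fold, 74% of 16-fold, 96% of 64-fold and 96% of 256-fold changes with 12 false calls. DESeq2 recovered 36%, 92%, 96% and 96% with 145 false calls. With its preset correlation camera gave a p under 0.05 for 0.5% of 200 random lists without a shift. The simulated genes were independent, so this does not cover lists whose members vary together. In the data the estimated correlation was 0.26 for gibberellin, 0.34 for cell cycle, 0.46 for ribosomal protein and 0.44 for photosynthesis genes. Further steps used Python 3.11.15 with scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.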

Results

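Stem RNA was compared between a tall and a short maize line (Zea mays), named high line (288) and low line (Chuan 29). With a single line of each height, differences tied to height cannot be told apart from other differences between these lines. Each line gave 2 libraries, taken at a developmental stage that the labels call big flare. The labels describe the plants as inbred lines in one field and as hybrids in another, and nothing in them says that the replicates were separate plants, so p-values measure only the spread between these samples, which may be technical. The deposited table held counts for 25633 genes. The totals were 64932808 reads in high replicate 1, 20935097 in high replicate 2, 24395101 in low replicate 1 and 20535283 in low replicate 2. Glycine-rich protein 1 (grp1, Zm00001d031168) was the most abundant transcript in 3 libraries, at 1.33% and 1.40% of the reads in high replicates 1 and 2 and 1.71% in low replicate 1, whereas sucrose synthase 1 (Zm00001d047253) led low replicate 2 at 0.80%.

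Replicates of a line resembled each other more than they resembled the other line. Across genes, which are not independent replicates, Pearson's r of log2 CPM (library-size-scaled counts) was 0.873 between the high-line libraries, 0.896 between the low-line libraries and 0.652 to 0.741 between lines. Replicates nevertheless differed far beyond sampling noise, with a chi-square per degree of freedom of 288 in the high line and 143 in the low line, so none was a duplicate of another. The biological coefficient of variation fitted to the 4 libraries was 56.9%.

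The stems of the lines differed most in genes that were well read in one line and almost or wholly unread in the other. Gene models of a RING/U-box protein, the small-RNA pathway gene ragged seedling 1 and an isocitrate dehydrogenase were well read in the high line. They had 0 reads in the low line. Models of leucine aminopeptidase 2 and a proteasome alpha subunit were nearly confined to the low line in these libraries. Each of the models named here shares a gene identifier with 1 other model. Their values hold for the model and not for the gene as a whole. Among abundant transcripts, a basic endochitinase, an auxin efflux carrier and a beta-expansin 4 gene (Zm00001d019560) were higher in the high line, and auxin response factor 4 was lower. Of 23360 genes tested, 185 were higher and 132 lower in the high line at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the smallest adjusted p being 0.0354. All 317 of these genes changed at least 2-fold, the smallest absolute log2 fold change being 2.59, and their values did not overlap between the lines. Non-overlap alone was common, at 13091 tested genes, and chance gives it to 33.3% of genes with 2 libraries against 2. An unadjusted p under 0.05 was common too, at 5213 of the 23360 tested genes by edgeR. Such counts within a gene list below are to be read against that share.

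The count of called genes was sensitive to the libraries and to the test. Without high replicate 1 the test called 103 higher and 86 lower genes, and without high replicate 2, low replicate 1 or low replicate 2 edgeR called 0 genes, although 4748, 4468 and 3044 genes had an unadjusted p under 0.05 there. DESeq2 called 2111 higher and 1610 lower genes, and all 317 edgeR calls were among them. Limma-voom called 706 higher and 581 lower genes.

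**Figure D1:**
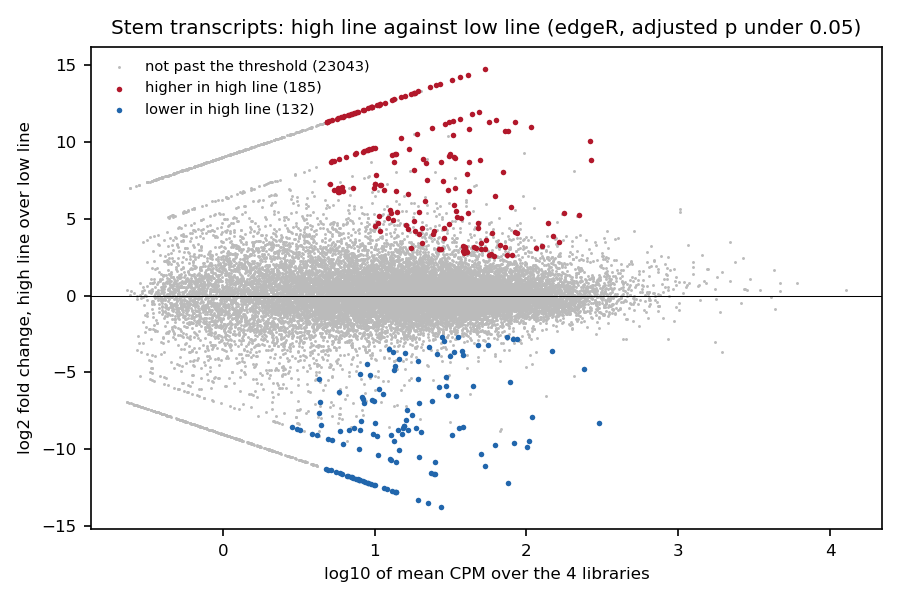
Each point is a gene, with the log10 of its mean CPM over the 4 libraries on the horizontal axis and the edgeR log2 fold change of the high line over the low line on the vertical axis. Red marks the 185 higher genes, blue the 132 lower genes and grey those that did not pass, and the straight edges are genes with 0 reads in one line, whose fitted fold change depends on the prior count.

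Genes read in a single line made up a large part of the edgeR calls. That share depends on the test, which recovered 6% of 4-fold but 96% of 64-fold changes in simulated counts. DESeq2 called 2111 higher and 1610 lower genes, and single-line genes can be only a small part of those. By a definition chosen after the data were seen, at most 3 reads over both libraries of one line and at least 100 in each library of the other, 148 genes were read in the high line only and 104 in the low line only. The first group held 83 of the 185 higher genes (44.9%) and the second 61 of the 132 lower genes (46.2%), and 97 and 61 genes had 0 reads in the other line. These genes were of middling abundance, with a median of 12.8 CPM in the high line and 11.3 CPM in the low line.

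Among called genes of at least 10 CPM with an informative description, the 8 largest fitted rises all had 0 reads in the low line. So did genes without such a description that had higher bounds, such as Zm00001d018257 (at least 1690-fold). Each fold is a lower bound set against a floor of 3 reads over both low-line libraries. Fitted values of such genes depend on the prior count, so their order is not a ranking. An alpha-mannosidase gene (Zm00001d032090), with 2 reads in the low line, had a ratio of 3320 (95% counting interval 919 to 27400). The RING/U-box superfamily gene (Zm00001d024560) reached 72.8 ± 31.0 CPM in the high line (SD, n = 2) and was at least 1150-fold higher there. Ragged seedling 1 (rgd1, Zm00001d041788), which acts in the trans-acting small-RNA pathway of leaf polarity, stood at 50.8 ± 11.3 CPM and was at least 805-fold higher. The gene for 65-kDa microtubule-associated protein 3-like (Zm00001d047347), of a family that bundles microtubules, stood at 38.7 ± 22.2 CPM and was at least 614-fold higher. Isocitrate dehydrogenase 2 (idh2, Zm00001d046262) had 36.6 ± 7.61 CPM and was at least 579-fold higher. The remaining genes were gamma-glutamylcyclotransferase 2-2-like (Zm00001d010554), plant UBX domain-containing protein 4 (Zm00001d025628), a probable peroxisomal acyl-activating enzyme 1 (Zm00001d035070) and an aldo/keto reductase (Zm00001d032921), at least 549-, 476-, 391- and 364-fold higher. Their adjusted p lay between 0.0354 and 0.0421 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The RING/U-box, rgd1, idh2, microtubule-associated and gamma-glutamylcyclotransferase models share a gene identifier with 1 to 3 other models, so reads may have been split among near-identical copies and their levels are uncertain.

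Among called genes of at least 10 CPM with an informative description, the 8 largest fitted falls were read almost only in the low line. Genes without such a description had higher bounds, such as Zm00001d044915 (at least 1500-fold lower in the high line). Leucine aminopeptidase 2 (Zm00001d014290), the DNA-damage-repair/toleration protein DRT102 (Zm00001d044548) and a polyprotein gene (Zm00001d050550) had 0 reads in the high line and were at least 762-, 751- and 661-fold lower there. DWARF AND LOW-TILLERING (Zm00001d017129), named after a rice GRAS protein of brassinosteroid signalling, stood at 49.6 ± 14.7 CPM in the low line (SD, n = 2) and had 2 reads in the high line, a ratio of 2100 with a 95% counting interval of 581 to 17400. A ubiquitin-conjugating enzyme E2 38 gene (Zm00001d015028), a putative replication protein (Zm00001d025697) and an isoflavone reductase homolog (Zm00001d041746) each had 1 read in the high line, with ratios of 3990 (715 to 158000), 2360 (423 to 93400) and 2080 (373 to 82300). These intervals and floors cover counting error only. The proteasome subunit alpha gene (Zm00001d017336) stood at 106.5 ± 11.5 CPM in the low line and 0.0313 ± 0.0442 CPM in the high line, a log2 fold change of -11.10 (SE 0.81). Adjusted p for these 8 genes ranged from 0.0354 to 0.0380 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The leucine aminopeptidase, polyprotein and proteasome models each share a gene identifier with 1 other model.

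Gibberellin genes, which include biosynthesis enzymes, receptors and DELLA repressors of a hormone that drives stem elongation, had a median log2 fold change of 1.04. Camera gave an adjusted p of 0.0015 over the 18 lists tested with its preset correlation. That call was lost, at adjusted p = 0.929 with an estimated correlation, and over the 11 settings tried the adjusted p ran from 2.03e-05 to 0.929. It was 0.382 without low replicate 2, which stood apart for this list at -1.14 relative to the mean of the libraries, against -0.05 in low replicate 1 and 0.57 and 0.66 in the high line. Photosynthesis genes were also lowest in that library (-2.51). Of 46 members tested, 0 rose and 0 fell over all genes by edgeR, 15 had an unadjusted p under 0.05 in the upward and 1 in the downward direction, and DESeq2 called 12 higher and 2 lower. Adjusted over the list alone, 2 members were higher, a pair of GID1L2 genes (Zm00001d005909, log2 fold change 2.63, SE 0.42, and Zm00001d022101, 5.91, SE 0.96). The 18 members described as GID1L2, a name given to carboxylesterase-fold relatives of the gibberellin receptor, had a median of 1.58, against 0.37 for the 28 others, a division made after the values were seen.

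Of the auxin genes, 1 rose and 1 fell by edgeR. At an unadjusted p under 0.05 there were 18 upward and 11 downward of 122 members, against 5213 of all 23360 genes tested. DESeq2 called 13 higher and 9 lower. Auxin efflux carrier component 1a (PIN1b, Zm00001d018024), which carries auxin out of cells, rose by 3.26 on the log2 scale (SE 0.40), from 23.9 ± 4.26 CPM in the low line to 229 ± 21.2 CPM in the high line (SD, n = 2 each; adjusted p = 0.0436, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Auxin response factor 4 (ARF4, Zm00001d001945), a transcription factor of the auxin response, fell by 4.85 (SE 0.48), from 25.8 ± 0.580 to 0.888 ± 0.137 CPM (adjusted p = 0.0380, same test). The other 120 of 122 members did not pass, the same 1 higher and 1 lower gene passed when adjusted over the list alone, and the list as a whole had a median of 0.14 (camera adjusted p = 0.773).

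Among the other hormone lists, ethylene had 1 riser of 93 members, the ethylene response factor Zm00001d020595, at 90.9 ± 34.7 CPM in the high line against 4.36 ± 0.167 in the low line (SD, n = 2; log2 fold change 4.38, SE 0.46). At an unadjusted p under 0.05 there were 16 upward and 6 downward ethylene genes, and 11 and 6 by DESeq2. When adjusted over the list alone, 1 ethylene gene was higher and 1 lower, the latter an ethylene response element binding protein (Zm00001d018305, 0.0234 CPM in the high line and 8.84 CPM in the low line). None of 51 cytokinin genes passed over all genes by edgeR, with 6 upward and 4 downward at an unadjusted p under 0.05 and 6 and 3 called by DESeq2. Adjusted over the list alone, 3 cytokinin genes were higher and 2 lower, led by a cytokinin riboside 5'-monophosphate phosphoribohydrolase (Zm00001d021450, 5.65, SE 0.79), an enzyme class that releases active cytokinin. None of 36 jasmonate genes passed over all genes by edgeR, with 10 upward and 4 downward at an unadjusted p under 0.05 and 6 and 4 called by DESeq2. Of the jasmonate genes, 2 were higher and 2 lower when adjusted over the list alone. They included allene oxide synthase 1 (aos1, Zm00001d028282), of jasmonate synthesis, at 608.8 ± 95.7 CPM in the high line and 53.4 ± 6.42 CPM in the low line. None of 25 brassinosteroid genes passed by edgeR either over all genes or adjusted over the list alone, with 3 upward and 1 downward at an unadjusted p under 0.05 and by DESeq2. The pattern of that list does not match DWARF AND LOW-TILLERING, described above. The medians of the ethylene, cytokinin, jasmonate and brassinosteroid lists were 0.14, 0.04, 0.40 and 0.00 (camera adjusted p = 0.338, 0.773, 0.410 and 0.897). Ethylene was at 0.0038 without low replicate 1 and pointed down without low replicate 2 (0.971).

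The cell wall lists had positive medians. They did not pass as groups in the main camera test, with its preset correlation, all libraries and the line as the only term. Without low replicate 1, wall loosening and lignin were each at adjusted p = 0.0103, and without low replicate 2 both pointed down (0.963 and 0.971). Wall loosening was at 0.0444 with domain names. Beta-expansin 4 (expB4, Zm00001d019560), a wall-loosening protein, was the 1 riser of 82 wall-loosening genes, with 266 ± 136 CPM in the high line and 10.1 ± 2.14 in the low line (SD, n = 2; log2 fold change 4.71, SE 0.59), and the list had a median of 0.78 (camera adjusted p = 0.138). Zm00001d019560 was also the 1 gene higher when adjusted over the list alone. Another gene described as beta-expansin 4 (Zm00001d017494) did not pass. It had 204.4 and 0.0527 CPM in high replicates 1 and 2 and 11.8 and 0 CPM in low replicates 1 and 2. Wall-loosening genes numbered 13 upward and 3 downward at an unadjusted p under 0.05 and 10 and 3 by DESeq2. Cinnamyl alcohol dehydrogenase 1 (cad1, Zm00001d002346), of the enzyme class that makes lignin alcohols, rose by 6.18 (SE 0.68) to 42.1 ± 22.1 CPM from 0.573 ± 0.210, the only one of 57 lignin and phenylpropanoid genes to pass (list median 0.28, camera adjusted p = 0.338). In that list 9 were upward and 3 downward at an unadjusted p under 0.05, and 9 and 4 by DESeq2. Adjusted over the list alone, 3 lignin genes were higher, cad1, a spermidine hydroxycinnamoyl transferase (Zm00001d018367, 3.02, SE 0.41) and dirigent protein 1 (Zm00001d048814, 5.31, SE 0.85), and 1 was lower, a phenylalanine ammonia-lyase (Zm00001d003015) at 0.0234 CPM in the high line and 13.9 ± 9.60 CPM in the low line. Of 59 cellulose and secondary wall genes, 0 rose and 0 fell by edgeR, also adjusted over the list alone, against 9 upward and 4 downward at an unadjusted p under 0.05 and 7 and 3 by DESeq2 (median 0.22, camera adjusted p = 0.402).

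Cell cycle and replication genes had a median log2 fold change of -0.67 over 209 members (camera adjusted p = 0.000193), and ribosomal protein genes -0.46 over 329 (camera adjusted p = 0.000704). Both group calls were lost, at adjusted p = 0.929 with an estimated correlation for each list, and also without high replicate 1, at 0.350 for cell cycle and 0.452 for ribosomal proteins. The cell cycle list had 0 rising and 0 falling by edgeR, also adjusted over the list alone, 10 upward and 36 downward at an unadjusted p under 0.05, and 6 higher and 27 lower by DESeq2. Of the ribosomal protein genes 1 rose and 2 fell, while 22 were upward and 49 downward at an unadjusted p under 0.05, and 9 and 28 by DESeq2. Over the 11 settings the adjusted p ran from 1.86e-11 to 0.929 for cell cycle and from 1.10e-10 to 0.929 for ribosomal proteins. The deepest library, high replicate 1, stood apart in both lists, with median log2 gaps to high replicate 2 of -1.29 for cell cycle and -0.82 for ribosomal proteins, against -0.27 and 0.17 between the low-line replicates. The ribosomal riser was 40S ribosomal protein SA (Zm00001d027919, log2 fold change 6.63, SE 0.83), and the genes that fell were 40S S4-C (Zm00001d020209, -5.95, SE 0.47) and 40S S21 (rps21b, Zm00001d029124, -5.87, SE 0.51), of which those that fell were also the 2 lower genes when adjusted over the list alone. SA and S4-C share identifiers with other models and their levels are uncertain.

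Photosynthesis genes, included as markers of green tissue, had the largest median shift of the lists with a set test. Over 65 members the median was 1.97, 51 had a positive fold change, and camera gave an adjusted p of 0.000193. This call was also lost, at adjusted p = 0.929 with an estimated correlation, and over the 11 settings the adjusted p ran from 5.66e-08 to 0.929, with 0.0572 without high replicate 1. By edgeR 0 members rose and 0 fell over all genes, against 18 upward and 3 downward at an unadjusted p under 0.05 and 24 and 3 by DESeq2. Adjusted over the list alone, a photosystem I reaction centre subunit XI gene (Zm00001d039687, 191 ± 169 CPM in the high line against 0.289 ± 0.343 in the low line, SD, n = 2) was the 1 higher gene and an NADP-dependent malic enzyme-like gene (Zm00001d003090, 0.0547 ± 0.0773 against 16.6 ± 9.69 CPM) the 1 lower gene. The marker level also varied within lines: the list median was 1.19 higher in high replicate 1 than in high replicate 2, and 2.38 higher in low replicate 1 than in low replicate 2. Lignin and ethylene medians moved with it, at 0.77 and 0.36 in the high line and 1.57 and 1.25 in the low line, and so did gibberellin in the low line (0.76) but not in the high line (-0.03).

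**Figure D2:**
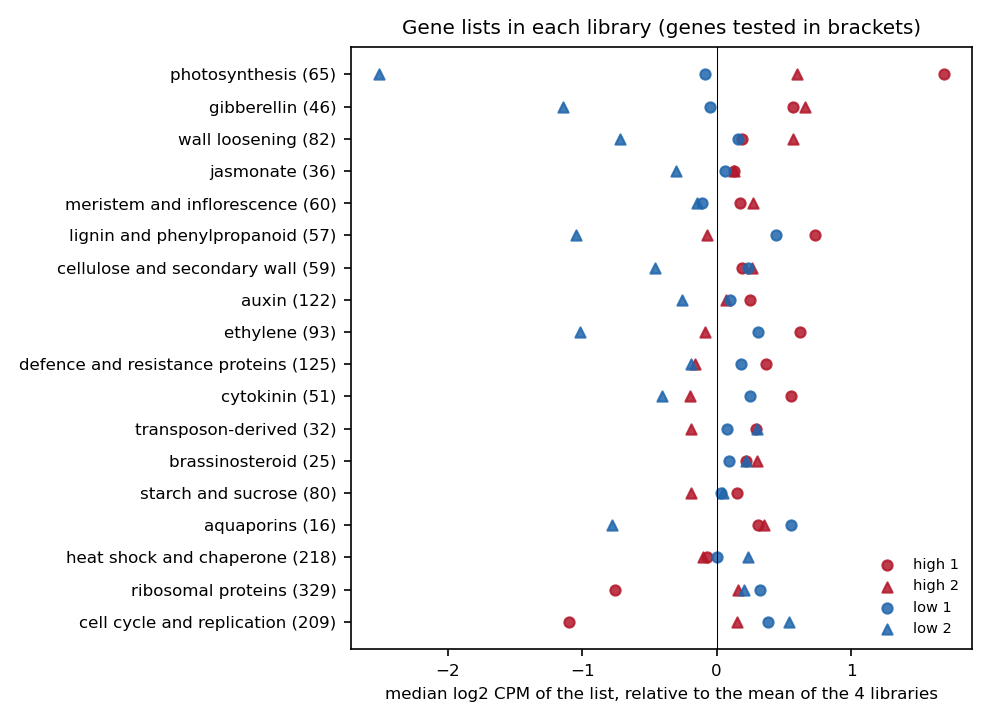
Each line of the plot is a gene list, with the number of tested genes in brackets, and each symbol is the median log2 CPM of the list in 1 library relative to the mean of the 4 libraries; red is the high line, blue the low line, circles are replicate 1 and triangles replicate 2. Low replicate 2 lies far to the left for photosynthesis, at -2.51, and high replicate 1 lies to the left of the other libraries for cell cycle, at -1.10.

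The other tissue markers gave little. None of 60 meristem and inflorescence genes passed by edgeR, also adjusted over the list alone, with 12 upward and 8 downward at an unadjusted p under 0.05 and 7 each by DESeq2 (median 0.33, camera adjusted p = 0.702). Seed storage had 3 tested genes, too few for a set test, with a median of 1.68. Among them globulin 1 (glb1, Zm00001d003801), a kernel storage protein, was the 1 gene higher when adjusted over the list alone, at 3.80 ± 1.94 CPM in the high line (SD, n = 2) and 0 reads in the low line.

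Of 125 defence genes, 5 rose and 1 fell by edgeR. There were 17 upward and 13 downward at an unadjusted p under 0.05 and 11 and 7 by DESeq2. Basic endochitinase (Zm00001d027524), which cleaves chitin, rose by 8.81 (SE 0.69), to 535 ± 102 CPM from 1.18 ± 0.474 (SD, n = 2; adjusted p = 0.0354, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The other 4 risers encode disease resistance proteins of the intracellular receptor class: RGA1 (Zm00001d048665 at 18.4 ± 6.30 CPM and Zm00001d023330 at 10.8 ± 2.58 CPM in the high line, both at 0.0190 CPM in the low line), RGA3 (Zm00001d023317, 31.5 ± 13.2 against 1.57 ± 0.240 CPM) and RPP13-like protein 3 (Zm00001d018786, 9.97 ± 0.526 CPM against 0 reads). The gene that fell, RPM1 (Zm00001d024978), had 0 reads in the high line and 19.9 ± 2.73 CPM in the low line, at least 551-fold lower. Adjusted over the list alone, 5 were higher and 2 lower, and the list as a whole did not pass (median 0.14, camera adjusted p = 0.714).

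Among the remaining lists, 2 genes of the starch and sucrose list rose by edgeR, both trehalose phosphate synthases. The list held 7 upward and 4 downward at an unadjusted p under 0.05 and 6 and 3 by DESeq2. Trehalose-phosphate synthase 9 (Zm00001d052060), of a pathway tied to sugar signalling, rose by 2.70 (SE 0.35), to 102 ± 3.93 CPM from 15.7 ± 2.37 (SD, n = 2), and trehalose-6-phosphate synthase 11 (Zm00001d018342) by 2.64 (SE 0.35), to 129 ± 13.4 CPM from 20.7 ± 2.05. They were the 2 risers of 80 members, and adjusted over the list alone 6 were higher, with invertase 2 (ivr2, Zm00001d014947, 707 ± 366 against 56.1 ± 4.61 CPM) among them. For this list the median was -0.23 and the mean 0.07, so their signs differed, and the set test pointed down without passing (camera adjusted p = 0.773). Co-chaperone SBA1 (Zm00001d049305), a partner of heat shock protein 90, fell by 2.85 (SE 0.36), to 20.9 ± 2.47 CPM from 151 ± 19.4. Among 218 heat shock and chaperone genes (median -0.28, camera adjusted p = 0.138), it alone passed edgeR's test over all genes. It did not pass when adjusted over the list alone, where 0 genes did by edgeR, against 10 upward and 32 downward at an unadjusted p under 0.05 and 10 and 22 by DESeq2. A hAT transposon gene (Zm00001d037780) was the 1 riser of 32 transposon-derived genes, over all genes and adjusted over the list alone, at 44.2 ± 19.8 against 0.236 ± 0.0658 CPM (list median 0.02 and mean -0.10, of opposite sign, camera adjusted p = 0.668, and 0.00965 with domain names). Its genes were upward in 1 case and downward in 4 at an unadjusted p under 0.05, and DESeq2 called 2 each way. None of 16 aquaporins passed by edgeR, adjusted over the list alone or over all genes, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 (median -0.24 and mean 0.03, again of opposite sign, camera adjusted p = 0.996).

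Of the maize stature and stem genes looked up by symbol, 10 symbols matched 11 gene models and none passed edgeR's test, with 2 at an unadjusted p under 0.05 and 2 called by DESeq2. The nearest was a DELLA gene named d9 (Zm00001d013465), a repressor of gibberellin growth responses, with 275 ± 53.8 CPM in the high line and 70.3 ± 8.88 in the low line (SD, n = 2; log2 fold change 1.97, SE 0.41). Its adjusted p was 0.0863 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and 0.000128 by DESeq2. A second model under that name (Zm00001d033680) had 1.05 (SE 0.44). Both models carry the same gene identifier and are described as DWARF8-like, and the symbol d8 itself was not matched. Which model is d8 and which is d9 was therefore not settled, and their reads cannot be assigned firmly. Dwarf plant 1 (d1, Zm00001d039634), the gibberellin 3-oxidase that makes active gibberellin, had 2.43 (SE 0.68; adjusted p = 0.135 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0.0135 by DESeq2). Values for anther ear1 (an1), dwarf plant 3 (d3) and the steroid reductase gene na1 were 1.39 (SE 1.02), 0.74 (SE 0.64) and 1.01 (SE 0.42). Those for knotted 1 (kn1), compact plant2 (ct2), the cinnamyl alcohol dehydrogenase gene bm1, vt2 and brittle stalk 2 (bk2) were -2.13 (SE 1.13), -0.43 (SE 0.39), -0.15 (SE 0.74), -0.04 (SE 0.64) and 0.02 (SE 2.35). The standard error of bk2, a COBRA-like gene of stalk strength, reflects levels of 128.5 and 4.75 CPM in high replicates 1 and 2 and 131 and 0.236 CPM in low replicates 1 and 2.

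**Figure D3:**
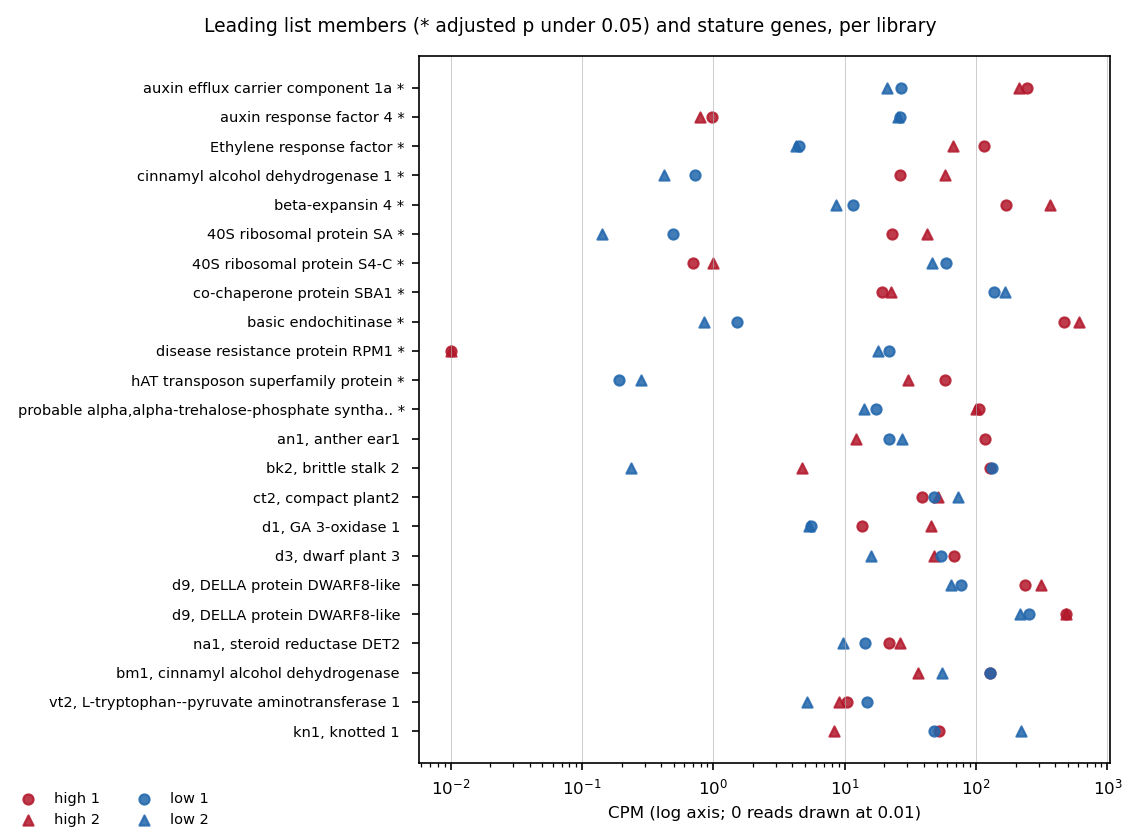
Each symbol is the level of a gene in 1 library in CPM on a log axis; red is the high line, blue the low line, circles are replicate 1 and triangles replicate 2, and 0 reads are drawn at 0.01. Starred genes, the member of each list with the smallest adjusted p in each direction, keep the lines apart, as every called gene did. By contrast, bk2 spans 0.236 to 131 CPM between the low-line replicates.

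The authors' deposited table marked 6022 genes as changed, 3321 up and 2701 down in the high line, which is the set with an unadjusted p under 0.05 and an absolute log2 fold change of at least 1. At a false discovery rate under 0.05 the authors' deposited table held 3554 genes, 2031 up and 1523 down, and gave no rate for 994 genes. All 317 edgeR calls were in that set, 0 of them with the opposite sign. The deposited comparison is named for DESeq2, and DESeq2 as run here also gave no rate for 994 genes. This overlap is therefore not a check separate from the DESeq2 alternative above. Across genes, Pearson's r between the authors' deposited log2 fold changes and the edgeR values was 0.958.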

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

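The tests on thinned counts, FPKM values, domain-matched lists and other thresholds for genes read in a single line were chosen after the results were seen. All 317 called genes kept the sign of their fold change in every setting fitted across genes. This could hardly be otherwise, because each had both libraries of one line above both of the other. Counts of higher and lower genes stayed within 1.5 times of 185 and 132 under both other scalings, both other filters, glmTreat, a 2-fold minimum and thinning. They were 2111 and 1610 with DESeq2, 706 and 581 with limma-voom, and 437 and 339 with limma on FPKM; the cause was not tested. With the replicate number as a block they were 1168 and 731. The labels do not say that a number pairs libraries, and differences between replicates correlated across genes at 0.394 between the lines. Leaving out each library in turn gave 0 to 103 higher and 0 to 86 lower genes, with 1 residual degree of freedom and the lone library assumed to vary like the other line. The count was 103 and 86 without high replicate 1 and 0 without any of the others, with smallest adjusted p of 0.0658, 0.142 and 0.170 and 4748, 4468 and 3044 genes at an unadjusted p under 0.05. Median log2 fold changes of all genes moved by over 0.1 from 0.017 in 3 settings, to 0.123 without low replicate 1, -0.09 without high replicate 1 and -0.118 with FPKM. Of the lists, 4 passed in the main test, 0 with an estimated correlation and 0 with fry, whose null differs, and 1 to 8 with a library left out. Gibberellin was at adjusted p = 0.929 with an estimated correlation, 0.459 with fry and between 2.03e-05 and 0.382 with a library left out. Cell cycle, ribosomal and photosynthesis lists were each at adjusted p = 0.929 with an estimated correlation and 0.724 with fry. With a library left out they ranged from 1.86e-11 to 0.350, 1.10e-10 to 0.452 and 6.01e-07 to 0.0572. Lists that passed only elsewhere were ethylene (0.0038 to 0.971 with a library left out), lignin (0.0103 to 0.971), wall loosening (0.0103 to 0.967, 0.0444 with domain names and 0.0381 with the block), heat shock (0.0261 to 0.825) and transposon-derived genes (0.00965 with domain names); the cause was not tested. Of 39 values of named genes, 28 were called in the main test, and those of the 11 stature models were not. Every called gene lost the call, with its direction kept, without high replicate 2, low replicate 1 or low replicate 2. Some also lost it without high replicate 1. With DESeq2, 0 lost the call and 2 of the stature models gained it. Genes read in the high or low line only numbered 97 and 61 at 0 reads in the other line and 322 and 244 at a minimum of 30 reads, which follows from the thresholds. With 2 libraries per line and the fitted spread, changes of 4-fold were mostly below what edgeR could call. In simulated counts with 0.1 times that spread, edgeR recovered 96% of 4-fold changes.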

Other observations

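The tests of protein families, of identifier order, of the division markers by replicate, of the replicate counts with a floor of 3 reads, of the replicate gap of photosynthesis genes and of 7 lists among the genes most different between replicates were chosen only after the results were seen. Several abundant transcripts outside the lists also separated the lines. A Bowman-Birk wound-induced proteinase inhibitor gene (Zm00001d040029) fell by 8.28 on the log2 scale (SE 0.95), to 1.86 CPM in the high line from 596 CPM in the low line, while another gene of that description (Zm00001d040027) rose by 3.02 (SE 0.34), to 94.98 from 11.7 CPM. A dehydrin (dhn2, Zm00001d051420), of a class tied to water deficit, fell by 5.63 (SE 0.43), to 3.10 from 153.5 CPM, and indole-3-glycerol phosphate lyase 1 (igl1, Zm00001d034460), which releases indole, fell by 3.19 (SE 0.36), to 10.98 from 100.2 CPM. A putative polyol transporter 1 (Zm00001d028151) rose by 5.22 (SE 0.64), to 432 from 11.6 CPM, and a probable mixed-linked glucan synthase 8 (Zm00001d021731), named for a grass wall polymer, rose by 3.61 (SE 0.38), to 99.9 from 8.18 CPM. Adjusted p for these 6 genes lay between 0.0354 and 0.0437 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Each gene had both libraries of one line above both of the other, as had all 317 called genes. The 16 benzoxazinoid genes, of maize's indole-derived defence compounds, had a median log2 fold change of 0.30.

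Protein families among the called genes were tested by Fisher's exact test against 19181 tested genes with a Pfam domain, with Benjamini-Hochberg adjustment over 910 families in each direction. Each exact combination of domains counted as a family. Of 7 genes annotated with both a protein kinase and a tyrosine kinase domain, 3 fell (Zm00001d024744, Zm00001d052584 and Zm00001d036656). This was the only family to pass (adjusted p = 0.00255, Fisher's exact test). Genes with the protein kinase domain alone (385 tested) or the tyrosine kinase domain alone (156 tested) did not pass. The result therefore covers these 7 genes and not kinase genes as a whole. Genes with an NB-ARC domain alone, the nucleotide-binding core of resistance receptors, were 5 of 83 among those that rose and did not pass (adjusted p = 0.177). Genes read in a single line less often had an informative description: 144 of 252 (57.1%) had none, against 25% of 17369 other genes with at least 100 reads in each library of a line (Fisher's exact test, odds ratio 4.0, p = 7.04e-27).

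The genes read in a single line could reflect reads assigned to a like-named copy in the other line, or chromosome segments that differ between the lines. Of 65 such genes with 1 to 4 genes of the same description, 2 had a copy read in the other line only, against 0 to 2 in the central 95% of 10000 random draws. They form the pair of acetamidase/formamidase genes Zm00001d009610 and Zm00001d043348. Of 95 such genes with a place in the gene table, 0 were neighbouring pairs, against 0 to 2 in random draws, but in the order of their identifiers, in which 93.8% of adjacent placed genes are also adjacent in that table, all 252 gave 8 pairs read in the same line, against 0 to 5 in 10000 draws (one-sided permutation test, p = 0.0006), among them Zm00001d039887 with Zm00001d039888 and Zm00001d007131 with Zm00001d007132. The wider test goes with segments for some of these genes, 7 of its 8 pairs lying within 10 numbers. The pairs hold only 16 of the 252, however. Every pair had a gene without an informative description, and whether adjacent models overlap or belong to the same gene was not tested. The copy count and the placed count met the bounds set against these explanations. They cover 65 and 95 of 252 (37.7% for the latter), too few to decide. Copies therefore cannot be told apart for these genes, and alleles that align poorly to the reference were not tested.

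The higher photosynthesis genes in the high line could come from a different share of green tissue in each library. Of the 68 list genes, 65 were read enough in these stems to be tested, the most abundant in the high line being CAB1 (Zm00001d021435, 1026 ± 82.3 CPM against 223 ± 234 in the low line, SD, n = 2) and ssu1 (Zm00001d052595, 641 ± 300 against 203.5 ± 224 CPM), and the gap between replicates of a line reached 2.38, larger than the 1.97 between lines. A second list of 31 leaf genes, fixed before its values were seen and sharing 0 genes with the first, had a median log2 fold change of 1.15 and was higher in replicate 1 of both lines, by 0.43 and 0.85, which is consistent with that explanation. Thinning high replicate 1 to the mean depth of the other libraries left the median at 1.95. Thinning keeps the expected CPM of a gene, so this median could hardly move. Greater depth, or a preparation difference that came with it, was therefore not decided by this test. A difference in greening between the lines themselves remains open and was not tested.

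Some large differences between replicates recurred in both lines: with a pseudocount of 2 reads, 46 genes were over 32-fold higher in replicate 1 than in replicate 2 of both, 0 were lower to that extent in both and 3 went opposite ways, and with counts under 3 taken as 3 reads these numbers were 36 (32 of the 46 among them), 2 and 1. Thinning high replicate 1 left the correlation of the replicate differences between the lines at 0.392. As thinning keeps expected CPM, this could hardly change, so greater depth of that library was not decided here either. Stems of another maturity under each number may be the source: the median gap of 46 secondary wall genes was 1.25 in the low line but -0.09 in the high line, which met the bound set beforehand against this explanation, yet was judged undecided after the value was seen because members went both ways (22 of 46 higher in replicate 1 of the high line; 12 over 2-fold higher in replicate 1 of both lines and 0 lower). The 80 division markers, kinesins, cyclins, replication licensing proteins and ribonucleotide reductases, were lower in replicate 1 of both lines. Their median gaps were -0.93 in the high line and -0.74 in the low line (17 over 2-fold lower in both lines and 0 higher). This goes with older stems under that number but was not among the bounds written. By name these markers are part of the cell cycle list. Its 209 tested genes had gaps of -1.29 in the high line but only -0.27 in the low line. The low-line shift was thus weaker over the full list, so the markers do not decide the question. Of the 46 most uneven genes, 1 was a secondary wall gene where 0.1 was expected (adjusted p = 0.232 over 7 lists, Fisher's exact test), too few to decide, with the bound of that test written after its result, and none of the other lists passed, defence being nearest with 2 where 0.23 was expected (adjusted p = 0.161); the labels do not say what the numbers mean.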
